A study of Homo sapiens with 6 samples.

How the data were processed

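Gene expression was measured by polyA RNA sequencing in 6 libraries of A375SM cells, a metastatic derivative of the human melanoma line A375. In 3 libraries the cells carried a control short hairpin RNA (shCtrl) and in 3 a hairpin against PRAME mRNA (shPRAME). Per the labels' protocols, RNA was extracted with TRIzol, enriched for polyA RNA and sequenced as read pairs of 150 bases on an Illumina NovaSeq. All 6 libraries carry the same batch label. The labels call the shCtrl libraries biological replicates and the shPRAME libraries replicates. They do not say whether these were separate transductions or separate cultures of the same transduced cells. P-values therefore measure only the spread between these libraries, which may be technical. The hairpin sequences and the number of hairpins are not given in the sources used here.

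The deposited files hold whole-number counts per NCBI gene identifier, 1 file per library, not normalized, per the file headers and the values themselves. The submitters' processing notes name fastp, STAR and Salmon and the builds GRCh38 and hg38, with no versions or roles. Which tool made the counts, the annotation release and whether the counting used strand are not given in the sources used here. Where the counts are rounded Salmon estimates, reads of near-identical genes were divided by a model. Genes with a near-identical copy, overlapping genes and antisense pairs are therefore uncertain.

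Each file had 40929 rows. Repeated gene identifiers, 34 rows, were added together, which left 40895. Of these, 40789 matched the RefSeq gene table of assembly GRCh38.p14, which supplied symbols, gene types and coordinates, and 106 did not. The unmatched identifiers took from 0.00778% to 0.00929% of a library's counts. Transcript length and GC content came from the longest GENCODE release 29 transcript of a gene. Library totals ranged from 30842788 to 34107332 counts, so that 1 gene at 3 counts, the limit a count of 0 allows, stood at 0.088 to 0.0973 CPM (counts scaled to the library total) in a single library. This floor covers counting error only.

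Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, glmQLFit and glmQLFTest, 2-sided), with group as the only term. Adjusted p-values are Benjamini-Hochberg values over all tested genes, and a gene passed at an adjusted p under 0.05. Levels are TMM-scaled CPM, given as mean ± SD of 3 libraries. A standard error of a log2 fold change was taken as the log2 fold change divided by the root of the quasi-likelihood F. For a gene with 0 counts in all libraries of a group, the fold is a lower bound against 3 counts over the whole group. For a gene with 1 to 3 counts in a group, the ratio has an exact binomial counting interval at the 95% level. TMM factors lay between 0.978 and 1.02.

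Before the data were examined, 50 gene lists were fixed from general knowledge of melanoma, of PRAME and of other cell types a culture can hold. Of their 1264 names, 1262 were found. Results of some listed genes are not reported here. Lists with at least 5 tested genes, 46 in number, were compared with all other genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. The genes named in the text were also set by a rule fixed before the data were examined: PRAME; the 12 largest and 12 smallest log2 fold changes among annotated genes that passed, with a mean of at least 5 CPM over all libraries and no overlap between the groups; up to 4 genes per list, namely the 2 with the smallest adjusted p in each direction at a mean of at least 1 CPM; and the 2 members with the highest mean CPM of each list of cell type markers. A gene named outside this rule is said to have been chosen after its values were seen.

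The test was run on simulated counts for the comparison of shPRAME with shCtrl. Counts were drawn for the 15954 tested genes from the means and depths of these libraries. The filter on low counts, applied again, left 15695 genes, and any changed gene it removed counts as not recovered. The test recovered 19 of 50 genes changed 1.2-fold, 37 of 50 changed 1.5-fold, 43 of 50 changed 2-fold and 49 of 50 changed 4-fold. It called 15 unchanged genes. In the simulated libraries, whose genes were drawn independently, the list test called the list of raised genes and none of 49 lists of unchanged genes. Genes of the real lists can be correlated (estimated correlation 0.35 for G2/M and mitosis). The simulation therefore does not measure how often such lists are called falsely.

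Alternatives fixed before the data were examined were RLE size factors, scaling to the library total only, no filter on low counts, a stricter filter (at least 1 CPM in at least 3 libraries), DESeq2 1.42.0, limma-voom, a test against a fold of 1.2 (glmTreat), the replicate number as a block, and leaving out each library. After the data were seen, 2 more were added: leaving out ribosomal RNA genes, and removing the regional shift, where the median log2 fold change of the 50 nearest expressed genes on the chromosome was entered as an offset. In simulated counts with chromosome 21 shifted by -0.8 on the log2 scale, the second estimated the shift at -0.79 and left 0 of the 135 calls on that chromosome.

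Positional tests used 9974 genes on the autosomes and chromosome X with an average log2 CPM of at least 3. Chromosome medians were set against 10000 random sets of genes of the same number. Chromosomes were split into segments of at least 20 genes, and a split was kept only where it exceeded all 1000 shuffles of the gene order. Near-identical transcripts were searched with BLAST 2.17.0. A copy was counted where another gene matched at least 80% of the longest transcript at 98% identity or more. Other calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9. Differences in the share of ribosomal and mitochondrial RNA were tested by exact permutation, which for 3 libraries against 3 cannot give a p under 0.1. Replicates of a group differed by more than sampling noise (chi-square per degree of freedom from 2.44 to 8.14), and none was merged. DNA copy number, protein levels and the raw reads were not analysed here.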

Results

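PRAME is a cancer-testis antigen that melanomas often express. It acts as a substrate receptor of the CUL2 ubiquitin ligase and has been described as a repressor of retinoic acid receptor signalling. The comparison of shPRAME with shCtrl cells asks how the transcriptome of A375SM melanoma cells that carry a hairpin against PRAME differs from that of cells with a control hairpin. Effects of the hairpin on other transcripts were not examined, so the differences below are between the 2 sets of cells and are not assigned to the loss of PRAME. Libraries held 34107332, 33439537 and 31525186 counts in shCtrl and 30842788, 33848375 and 33854545 in shPRAME. On average 20957 ± 81.6 genes had a count in shCtrl and 21439 ± 53.4 in shPRAME (mean ± SD, n = 3 each).

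PRAME mRNA in the knockdown cells stood at 34.2% of the control level. The gene (NCBI gene 23532, chromosome 22, 22547701 to 22559265, GRCh38) had 5623, 5356 and 5083 counts in the shCtrl libraries and 1803, 1993 and 1857 in the shPRAME libraries. Its level fell from 165.0 ± 1.26 to 56.4 ± 2.30 CPM (mean ± SD, n = 3 each), or 2.92-fold, with a log2 fold change of -1.55 (SE 0.0314, edgeR adjusted p = 4.85e-17). Every shPRAME library lay below every shCtrl library.

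**Figure D1:**
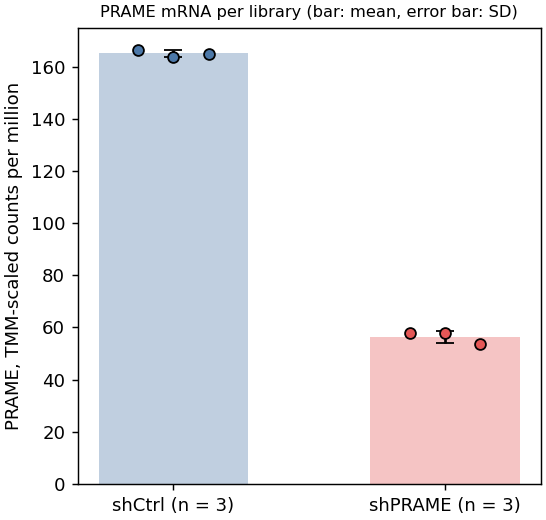
PRAME mRNA in TMM-scaled CPM in the 3 shCtrl and 3 shPRAME libraries (points), with bars for the group mean and error bars for the SD. The shCtrl libraries lie between 163.9 and 166.4 and the shPRAME libraries between 53.8 and 57.8.

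Knockdown and control cells differed over most of the transcriptome. Of 15954 genes tested, 11875 (74.4%) passed, 6008 higher and 5867 lower in shPRAME, and of these 1616 were at least 2-fold higher and 1345 at least 2-fold lower. Among protein-coding genes 10197 of 13063 passed, and among long noncoding RNA genes 1407 of 2402. The groups did not overlap at 76.5% of genes, where chance gives 10%. The first principal component, which separated the groups, held 89.9% of the variance, and the biological coefficient of variation within groups was 3.11%. Against a minimum fold of 1.2, 7726 genes passed.

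The largest increases were in genes with almost no reads in control cells. SOX11, a neural transcription factor (chromosome 2, 5692384 to 5701385), had 1 count over the 3 shCtrl libraries and reached 138.1 ± 1.57 CPM in shPRAME, a ratio of 13435 with a counting interval of 2411 to 530686. TFAP2B, a neural crest transcription factor (chromosome 6, 50818355 to 50847619), rose from 0.104 ± 0.0522 to 145.8 ± 1.77 CPM, and ROBO1, an axon guidance receptor (chromosome 3, 78597239 to 79767998), from 0.0726 ± 0.0214 to 122.5 ± 3.70 CPM. The sorting receptor gene SORCS1 reached 82.5 ± 3.82 CPM from 1 count over the control group (ratio 8013, counting interval 1438 to 316540). NTS, which encodes neurotensin, reached 26.1 ± 1.35 CPM and ADGRL2, an adhesion receptor, 23.6 ± 2.09 CPM, each also from 1 count. Genes without a count in any shCtrl library were PAGE2 (51.5 ± 0.915 CPM in shPRAME, at least 1672-fold higher), PDE3B (30.9 ± 2.28 CPM, at least 998.4-fold), PCDH7 (29.8 ± 0.876 CPM, at least 965.8-fold), COL1A2 (21.6 ± 1.31 CPM, at least 698.1-fold), GALNT13 (15.6 ± 0.347 CPM, at least 506.2-fold) and ZNF700 (10.5 ± 0.356 CPM, at least 339.8-fold). Genes had to pass to be named here, and these 12 had edgeR adjusted p of 3.16e-14 or smaller.

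Among all genes that passed, 239 were at least 32-fold higher and 73 at least 32-fold lower. ADAMTS12, a secreted metalloprotease (chromosome 5, 33523535 to 33891990), fell from 21.3 ± 0.231 CPM to 3 counts over the 3 shPRAME libraries, a ratio of 712.4 with a counting interval of 243.4 to 3457. PASD1, a cancer-testis antigen, fell 332.5-fold from 31.1 ± 0.189 CPM, and SRGN, the proteoglycan serglycin, 127.6-fold from 24.7 ± 1.31 CPM. MAGEA10, another cancer-testis antigen (chromosome X, 152133310 to 152138577), fell from 38.4 ± 0.467 to 0.690 ± 0.0953 CPM. SLC16A3, the lactate exporter MCT4 (chromosome 17, 82217934 to 82240086), fell from 80.2 ± 3.83 to 2.23 ± 0.364 CPM, or 36.0-fold. LINC02953, PIK3CG, NFASC, MYEOV, SULF2 and ADGRE1 fell 32.8-fold to 48.9-fold. U2AF1, a splicing factor gene, had 35.4 ± 5.21 CPM in shCtrl and no count in shPRAME, at least 1181-fold lower, but this gene is uncertain. It has a near-identical copy on chromosome 21, LOC102724594, which is named after its values were seen. The 2 genes together had 96.9 CPM in shCtrl and 75.6 in shPRAME. The 12 genes, which also had to pass to be named, had edgeR adjusted p of 9.70e-15 or smaller.

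**Figure D2:**
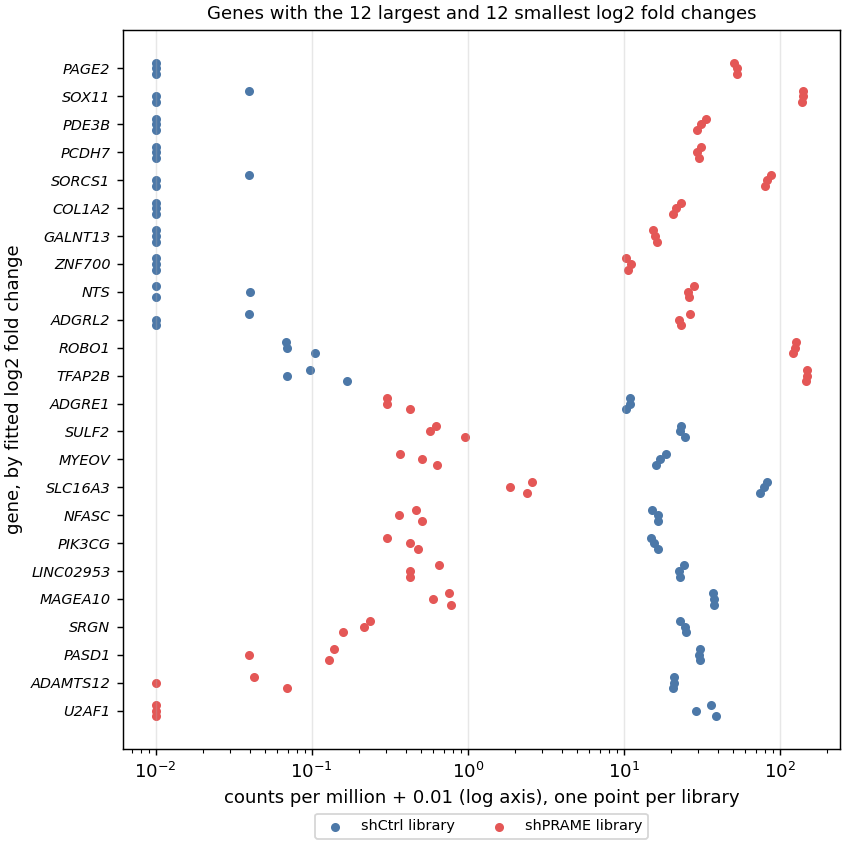
CPM plus 0.01, on a log axis, of the 12 genes with the largest and the 12 with the smallest log2 fold change, with 1 point per library (blue, shCtrl; red, shPRAME; n = 3 each). For each gene the 3 libraries of a group lie together and, as the naming rule requires, apart from the other group. No count in any shCtrl library was found for 6 genes.

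Interferon-stimulated genes were lower in the knockdown cells. Of 43 tested, 36 fell, 4 rose and 3 did not pass (37 fell and 4 rose when adjusted over the list alone), with a median log2 fold change of -1.25. IFIT3 fell from 53.3 ± 3.00 to 4.82 ± 0.149 CPM and IFITM3, a membrane protein that restricts viral entry, from 179.3 ± 5.21 to 66.3 ± 0.290 CPM. ISG20, an exonuclease gene, rose from 3.28 ± 0.180 to 4.42 ± 0.446 CPM. The list was called lower by camera (adjusted p = 3.04e-07, and adjusted p = 0.106 with an estimated correlation).

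Neighbouring immune lists were not called at the preset correlation. Of 21 genes of MHC class I antigen presentation, 14 fell and 5 rose (camera adjusted p = 0.0617). PSME1, a proteasome activator subunit, fell from 39.2 ± 0.613 to 23.6 ± 0.818 CPM and the peptide trimming enzyme ERAP1 from 100.2 ± 1.96 to 64.4 ± 2.00 CPM, while HLA-C rose from 41.1 ± 1.25 to 60.0 ± 1.88 CPM and HLA-B from 31.5 ± 0.990 to 39.7 ± 1.44 CPM. Of 11 class II genes 8 fell, among them the transactivator CIITA (8.41 ± 0.661 to 1.45 ± 0.122 CPM), and 2 rose. Of 24 NF-kB and cytokine genes 15 fell and 6 rose (adjusted p = 0.0896): ICAM1 fell from 90.7 ± 0.228 to 14.9 ± 0.282 CPM and TRAF1 from 26.4 ± 1.47 to 3.68 ± 0.223 CPM, and CXCL8, the chemokine interleukin-8, rose from 127.1 ± 4.15 to 640.5 ± 9.42 CPM. Among 14 immune checkpoint ligand genes 6 rose and 5 fell.

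Genes of mitosis were higher in shPRAME, with small changes. Of 66 genes of G2/M and mitosis, 52 rose, 8 fell and 6 did not pass (53 rose and 8 fell when adjusted over the list alone), with a median log2 fold change of 0.41, and 3 rose at least 2-fold. TOP2A, topoisomerase II alpha, rose from 688.7 ± 11.7 to 1494 ± 25.3 CPM and the spindle protein gene TACC3 from 83.2 ± 1.72 to 187.5 ± 4.54 CPM. HJURP fell from 219.0 ± 5.28 to 161.7 ± 3.02 CPM and KIF4A from 147.6 ± 2.80 to 115.6 ± 1.01 CPM; both lie in regions whose neighbouring genes shifted down, and with that regional shift removed, an alternative chosen after the data were seen, both were higher. Camera called the list higher (adjusted p = 5.23e-06, and adjusted p = 0.861 with an estimated correlation). Of 55 S phase genes 32 rose and 14 fell, and TYMS, thymidylate synthase, rose from 182.9 ± 6.54 to 464.7 ± 9.99 CPM (list not called, adjusted p = 0.244).

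All 13 mitochondrially encoded mRNAs rose, by log2 fold changes of 0.09 to 0.57 (median 0.24; the same 13 when adjusted over the list alone). MT-ND1, a subunit of respiratory complex I, rose from 1684 ± 89.2 to 2500 ± 33.5 CPM. Camera called the list higher (adjusted p = 0.0258, and adjusted p = 0.893 with an estimated correlation). These mRNAs together made up 3.91% ± 0.122 of counts in shCtrl and 4.65% ± 0.0614 in shPRAME. Nuclear ribosomal RNA took 4.82% ± 0.199 of counts in shCtrl and 2.501% ± 0.563 in shPRAME, and mitochondrial ribosomal RNA 0.690% ± 0.0195 and 0.483% ± 0.0172 (n = 3 each; exact permutation p = 0.1 for each of the 3 shares, the smallest that 3 against 3 can give).

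Extracellular matrix genes moved both ways, more of them up. Their summed level nevertheless fell, from 19338 CPM in shCtrl to 15123 CPM in shPRAME. FN1, fibronectin, a member of this list, fell from 7270 ± 143.9 to 4949 ± 56.3 CPM. Of 44 genes 28 rose, 12 fell and 4 did not pass (28 rose and 13 fell when adjusted over the list alone), with a median log2 fold change of 0.53 that was the same with COL1A2 at its lower bound, and 18 rose at least 2-fold. COL6A3 rose from 9.98 ± 0.0454 to 159.2 ± 1.32 CPM and COL5A1 from 1.82 ± 0.215 to 65.2 ± 2.22 CPM. COL4A1, a basement membrane collagen, fell from 913.4 ± 7.38 to 355.5 ± 5.002 CPM and COL8A1 from 24.9 ± 0.682 to 1.56 ± 0.257 CPM. Camera called the list higher (adjusted p = 0.0439, and adjusted p = 0.855 with an estimated correlation); without shPRAME replicate 1 the adjusted p was 0.0556. Several of the collagens are also markers of fibroblasts, of which 6 of 8 tested rose, all at least 2-fold, and 2 fell (median log2 fold change 3.04, camera adjusted p = 0.0950, not called). COL6A3 and PDGFRB had the highest levels of these markers, and PDGFRB fell from 64.3 ± 1.86 to 17.4 ± 1.32 CPM. COL1A2 is given above, and the other 5 tested markers are named after their values were seen. LUM rose from 1 count over the shCtrl group to 992 (ratio 963.2, counting interval 172.5 to 38081) and COL3A1 from 3 counts to 256 (ratio 82.9, counting interval 28.03 to 404.4). PDGFRA rose from 3.72 ± 0.224 to 12.3 ± 0.733 CPM and COL1A1 from 0.112 ± 0.0310 to 0.493 ± 0.100 CPM, while FAP fell from 46.1 ± 1.202 to 27.0 ± 0.771 CPM.

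**Figure D3:**
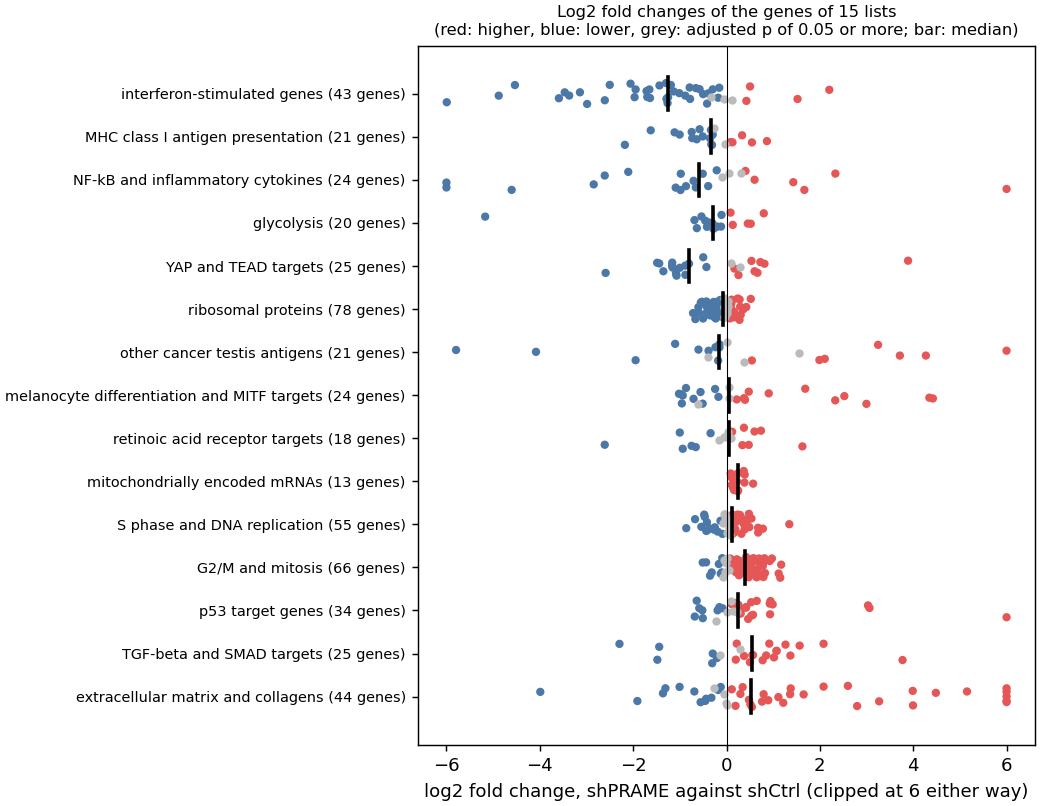
Log2 fold changes (shPRAME against shCtrl, clipped at 6 either way) of the genes of 15 of the lists, with red points for genes higher, blue for genes lower and grey for an adjusted p of 0.05 or more, and a bar at each median. The medians run from -1.25 for interferon-stimulated genes to 0.55 for TGF-beta and SMAD targets, and most lists have genes on both sides of 0.

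Lists tied to known roles of PRAME were not called. Of 18 retinoic acid receptor targets 8 rose, 6 fell and 4 did not pass (camera adjusted p = 0.987). DHRS3, a retinaldehyde reductase, rose from 46.3 ± 1.70 to 77.2 ± 1.63 CPM and the homeobox gene MEIS1 from 2.95 ± 0.302 to 9.13 ± 0.375 CPM, whereas RARG, retinoic acid receptor gamma, fell from 92.2 ± 2.97 to 48.2 ± 0.760 CPM. Of 15 genes of CUL2 ubiquitin ligases 8 rose and 4 fell, and CUL2 itself fell from 112.8 ± 3.73 to 75.1 ± 2.62 CPM (list adjusted p = 0.896). The balance of this list turned once the regional shift was removed, with 3 genes higher and 6 lower. Of 11 PRC2 subunits, the Polycomb complex that methylates histone H3, 3 rose and 3 fell (adjusted p = 0.941). Of 21 other cancer-testis antigens 7 rose and 10 fell (adjusted p = 0.974): MAGEC2 rose from 7.27 ± 0.505 to 68.9 ± 0.914 CPM and MAGEA4 fell from 802.7 ± 15.4 to 374.2 ± 4.83 CPM. Once the same shift was removed, 14 were higher and 5 lower, and the median log2 fold change turned from -0.15 to 0.20 (adjusted p = 0.155). Members of this family resemble one another, and their counts are uncertain to that extent.

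Melanoma state genes split as well. Of 24 melanocyte differentiation genes and MITF targets 11 rose and 10 fell (adjusted p = 0.941). ERBB3 rose from 322.2 ± 4.11 to 603.3 ± 12.3 CPM and the endothelin receptor EDNRB from 35.9 ± 1.75 to 115.5 ± 2.70 CPM, while GPNMB fell from 360.5 ± 0.705 to 182.7 ± 2.59 CPM and MYO5A, a melanosome motor, from 187.9 ± 5.61 to 96.8 ± 0.696 CPM. Of 39 genes of dedifferentiated and invasive melanoma 16 rose and 19 fell. CDH2, N-cadherin, rose from 50.2 ± 1.77 to 327.5 ± 0.512 CPM and TGFBI fell from 1094 ± 21.004 to 223.2 ± 5.60 CPM. Of 24 genes of the epithelial-mesenchymal transition 10 rose and 11 fell. That list mixes epithelial genes such as DSP with mesenchymal genes such as CDH2. It would split under a transition in either direction, so its counts do not decide whether one took place. Of 20 neural crest and stemness genes 9 rose and 9 fell, with FOXD3 falling from 9.78 ± 0.771 to 1.24 ± 0.320 CPM.

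Signalling lists were not called. Of 25 TGF-beta and SMAD targets 17 rose and 6 fell (camera adjusted p = 0.0754), with PMEPA1 rising from 401.9 ± 0.794 to 687.5 ± 4.55 CPM. Of 25 YAP and TEAD targets 8 rose and 15 fell, and PTPN14 fell from 301.1 ± 5.97 to 142.2 ± 2.97 CPM. Of 23 genes of MAPK output 8 rose and 7 fell: SPRY4, a feedback inhibitor, rose from 278.4 ± 5.30 to 675.5 ± 5.21 CPM and EPHA2 fell from 64.0 ± 3.16 to 23.2 ± 1.29 CPM. MYC rose from 18.2 ± 0.557 to 76.1 ± 1.03 CPM, and among 28 immediate early genes 12 rose and 11 fell. Of 16 Wnt targets 9 rose and 5 fell, with SOX4 rising from 11.4 ± 0.223 to 77.4 ± 3.64 CPM. Integrin and focal adhesion genes (17 rose and 12 fell of 35) included ITGA1, which rose from 74.9 ± 1.92 to 458.8 ± 29.1 CPM. Matrix proteases and inhibitors (13 and 7 of 24), angiogenic factors (8 and 8 of 18) and senescence-associated secreted factors (11 and 8 of 24) also split, and THBS1 fell from 2593 ± 94.1 to 690.3 ± 89.6 CPM.

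Growth and death genes gave 34 p53 targets of which 21 rose and 8 fell (camera adjusted p = 0.0626), with AEN rising from 40.4 ± 0.636 to 77.7 ± 1.24 CPM. Of 13 tested genes from a list of CDK inhibitors, D cyclins, CDK4, CDK6 and RB family genes, 4 rose and 7 fell. CDKN1C, the inhibitor p57, rose from 1.33 ± 0.143 to 12.9 ± 0.691 CPM and CDKN2C fell from 66.2 ± 1.07 to 18.3 ± 1.66 CPM. Death receptor genes (2 rose and 7 fell of 11), pro-apoptotic BCL2 family genes (7 and 5 of 12) and anti-apoptotic genes (3 and 5 of 10) were not called, and BIRC5, survivin, rose from 100.7 ± 2.84 to 191.0 ± 6.34 CPM.

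In metabolism, 15 of 20 glycolysis genes fell and 5 rose (camera adjusted p = 0.0617). After removal of the regional shift 11 were lower and 7 higher (camera adjusted p = 0.270). GAPDH fell from 3800 ± 59.5 to 2621 ± 28.2 CPM and HK2, hexokinase 2, rose from 97.97 ± 3.50 to 170.3 ± 2.86 CPM. Of 24 hypoxia genes 8 rose and 13 fell. Cholesterol synthesis genes (13 rose and 6 fell of 24) and fatty acid synthesis genes (8 and 4 of 15) included SREBF2, which rose from 52.7 ± 2.21 to 102.8 ± 0.163 CPM, and ELOVL6, from 31.6 ± 0.829 to 86.7 ± 2.48 CPM. Of 27 NRF2 and ferroptosis genes 9 rose and 16 fell, with FTL, ferritin light chain, falling from 766.8 ± 13.3 to 251.8 ± 7.21 CPM. Of 26 autophagy and lysosome genes 8 rose and 15 fell, and SQSTM1, the receptor p62, fell from 723.1 ± 17.8 to 228.7 ± 3.68 CPM. Nuclear-encoded oxidative phosphorylation genes (21 and 33 of 68), ATF4 targets (10 and 12 of 30), unfolded protein response genes (13 and 6 of 23) and heat shock genes (9 and 4 of 18) were not called. Unfolded protein response genes were evenly split after removal of the regional shift, with 10 higher and 10 lower.

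Of 78 ribosomal protein genes 19 rose and 41 fell (camera adjusted p = 0.0617); RPS25 rose from 276.2 ± 4.53 to 396.1 ± 8.15 CPM and RPS12 fell from 456.3 ± 11.0003 to 277.6 ± 0.758 CPM. MYC targets and ribosome biogenesis genes (18 and 12 of 39), replication-dependent histones (3 and 3 of 13) and the RNA interference machinery (6 and 7 of 13) were not called. With the regional shift removed 5 ribosomal protein genes were higher and 59 lower, 27 MYC target genes higher and 7 lower, and 1 gene of the RNA interference machinery higher and 5 lower. Of the RNA interference genes, DROSHA fell from 175.1 ± 1.15 to 130.4 ± 1.43 CPM and XPO5 rose from 103.7 ± 1.00 to 180.6 ± 1.91 CPM. Among markers of leukocytes 3 of 3 tested rose. CD68 rose from 43.9 ± 1.16 to 70.7 ± 0.767 CPM and LYZ from 0.0707 ± 0.0437 to 1.31 ± 0.155 CPM, and PTPRC, named after its values were seen, had no count in shCtrl and 0.925 ± 0.199 CPM in shPRAME. KRT10, the only keratinocyte marker tested, fell from 28.2 ± 1.08 to 23.4 ± 0.613 CPM. Of 2 endothelial markers TEK rose from 3 counts over the shCtrl group to 281, a ratio of 90.9 with a counting interval of 30.8 to 443.6, and KDR, which did not pass, stood at 0.335 ± 0.123 CPM in shPRAME. NEFL and GATA3, markers of HEK293 packaging cells, did not pass, at 3.49 ± 0.464 and 0.967 ± 0.0937 CPM in shPRAME.

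Over the 46 lists tested, camera with the preset correlation called 3 higher and 1 lower, and with an estimated correlation called 0, with 3 at an unadjusted p under 0.05. Counts adjusted over the list alone differed from those above for 5 lists, by 1 gene each. For 13 lists, none of them called, the median, the mean and the direction of the test differed in sign.

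Log2 fold changes also followed the position of genes, a relation examined after the data were seen. Of 111 expressed genes on chromosome 21, 101 fell and 6 rose, with a median of -0.77. Medians were 0.39 on chromosome 4, 0.38 on chromosome 18, 0.30 on chromosome 8, -0.34 on chromosome 13 and on X, and -0.30 on chromosome 5. The shift was a step within some chromosomes: on chromosome 1 the median was -0.35 over 420 genes up to 78.02 megabases and 0.04 over the 610 genes beyond, and on chromosome 2 it was 0.09 over 294 genes up to 95.3 megabases and -0.34 over the 395 beyond. Medians differed from those of random gene sets on 19 of 23 chromosomes (2-sided, Benjamini-Hochberg adjusted p = 0.0441 or smaller). PRAME lies on chromosome 22, where the median was 0.25. With the regional shift removed, 11362 genes passed and PRAME had a log2 fold change of -1.80; of the 9890 genes that passed both ways, 561 had the opposite direction.

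**Figure D4:**
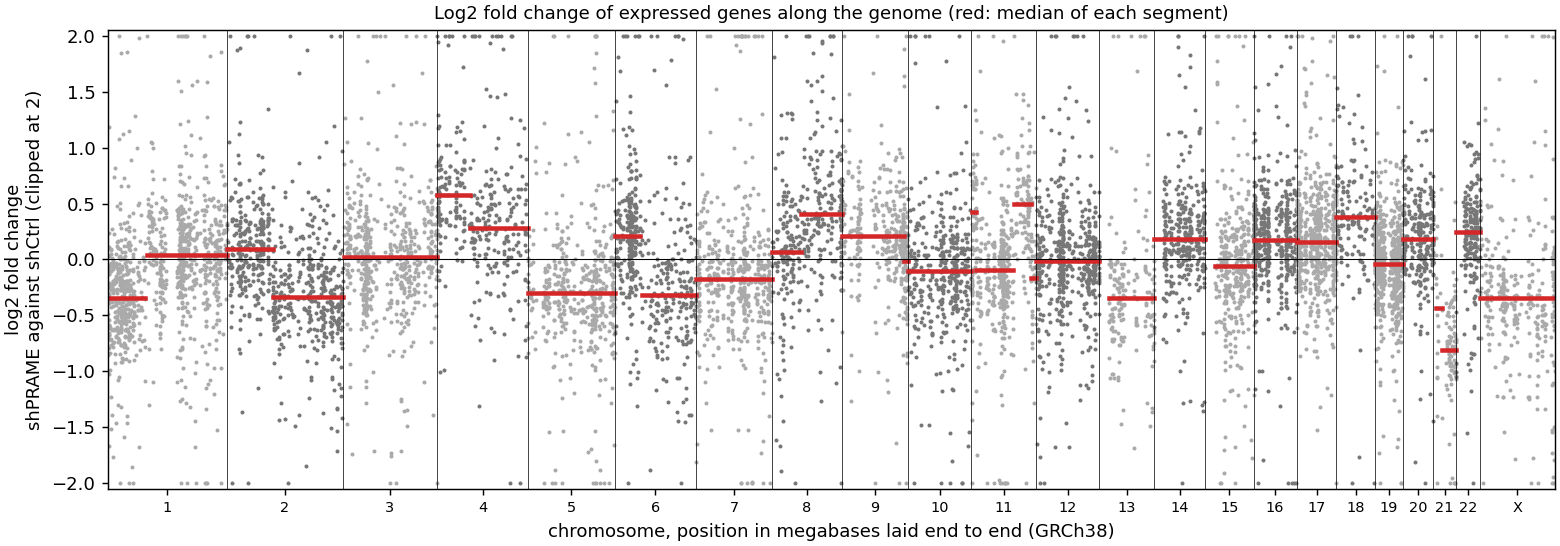
Log2 fold change (shPRAME against shCtrl, clipped at 2) of 9974 expressed genes by position on chromosomes 1 to 22 and X in megabases, with a red line at the median of each of 34 segments. Segments lie between -0.81 on chromosome 21 and 0.58 on chromosome 4.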

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

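Tests with the regional shift removed, ribosomal RNA left out and all counts at 2-fold under alternatives were chosen after the data were seen. PRAME stayed lower and past the threshold under 16 alternatives, with log2 fold changes from -1.80 to -1.50 (from -1.56 to -1.51 with 1 library left out) and adjusted p-values up to 3.21e-13. The number of genes changed stayed within 1.5 times of 11875 under 15 of 16, and was 11390 to 11704 with 1 library left out. Against a fold of 1.2 it was 7726, with 3921 higher and 3805 lower, since small changes no longer count. Genes at least 2-fold higher numbered from 1168 with the stricter filter to 2293 with no filter, and those at least 2-fold lower from 943 to 1846. The replicate numbers do not pair the libraries (correlations of deviations for the same number -0.0589, -0.119 and -0.0999), no library correlated best with its own number, and the replicate block gave 11603 genes changed.

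Gene lists depended on the test. With an estimated correlation 0 lists were called higher and 0 lower, and fry, which does not compare a list with other genes, called 22 higher and 19 lower. With the regional shift removed 6 were called higher and 4 lower. With 1 library left out, 2 to 3 were called higher and 1 to 4 lower; the 4 came without shCtrl replicate 3 (MHC class I, glycolysis and ribosomal proteins in addition), 2 came without shCtrl replicate 1, and matrix genes lost their call without shPRAME replicate 1 and with the stricter filter. The cause was not tested.

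Of 185 named genes past the threshold besides PRAME, 172 were called against a fold of 1.2 and 175 with the same direction after the regional shift was removed, where CHAF1B and AGO2 were among those that no longer passed. Most named genes were chosen by small adjusted p or large fold change, which favours keeping the call. Of all 11875 genes that passed, 7726 were called against a fold of 1.2. With the regional shift removed, 9329 of them were called in the same direction. IFITM1 no longer passed without shCtrl replicate 3, shPRAME replicate 1 or shPRAME replicate 2. With the regional shift removed the log2 fold change turned to -0.019 for JARID2, 0.076 for RBBP4, 0.094 for HJURP, 0.066 for KIF4A, 0.10 for ACSL3, -0.068 for RPL8 and 0.073 for HSPA4, by construction, since their neighbours had moved further the same way. Changes of 1.2-fold were recovered for 19 of 50 simulated genes. The simulation changed far fewer genes than passed in the data, which made its adjusted threshold stricter. Recovery in the data may therefore differ, and its dependence on depth or replication was not tested.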

Other observations

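The tests by other splits of the libraries, of a copy number difference along chromosomes and of a mixed cell population, and the removal of the regional shift, were chosen only after the results were seen.

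With the regional shift removed, camera brought further gene lists past the threshold, beside the 4 called without it. Ribosomal proteins (adjusted p = 1.37e-05), MHC class I antigen presentation (0.0187) and NF-kB and cytokine genes (0.0267) were then called lower. MYC targets and ribosome biogenesis (0.00939), cholesterol biosynthesis (0.0165) and p53 targets (0.0432) were called higher. For each of the 6 lists this was the lowest value among 12 alternatives, fry left out because it does not compare a list with other genes, and the highest adjusted p ranged from 0.612 to 0.893, with an estimated correlation. Interferon-stimulated genes (1.06e-07), G2/M and mitosis genes (3.86e-09) and matrix genes (0.000252) kept their directions, with adjusted p over the same 12 alternatives from 6.94e-08 to 0.106, from 3.86e-09 to 0.861 and from 0.000252 to 0.855. Mitochondrially encoded mRNAs, which have no regional shift of this kind, ranged from 0.00461 to 0.893.

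Libraries of 3 against 3 make 10 splits, too few for a share under 0.05. The real split gave 11875 genes changed and the highest of the 9 others 0 by edgeR (27 to 49 genes at an unadjusted p under 0.05, and at most 2 by limma-voom). Only 1 split, the real one, gave as many. Each of the others mixes libraries of both groups, so the difference between the groups enters their spread. Few calls in those splits follow from that, and the gene counts cannot decide whether the real count arose by chance. For gene lists the real split called 4 and the highest of the others also 4, so that 3 of 10 splits, the real one included, gave as many.

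Fold changes shifted together along chromosomes, in 34 segments of which 12 had a median of at least 0.3 in size, and the median of 25 neighbouring genes had an SD of 0.248 over 387 blocks, against at most 0.119 with the gene order shuffled. Differences between single libraries are too small as the whole cause: within groups the SD was at most 0.0375, or 15.2% of that between groups, although 4 of 6 libraries, each against the rest of its group, lay above all shuffled orders (shCtrl 1 and shCtrl 3 with 13 breaks each, and shPRAME 1 and shPRAME 3 at 0.0173 and 0.0166 against 0.0166 and 0.0161), with a largest chromosome median of 0.0483. A trend with GC content and transcript length is argued against for chromosome 21 only. The median of that chromosome was -0.754 before the trend was removed and -0.7485 after (interval -0.812 to -0.714). Other chromosomes were not examined in this way, so the trend stays open for them. Without the 795 genes changed at least 2-fold, the SD between groups was still 0.226, just over 2 times the highest of shuffled orders (0.107). A difference in DNA copy number between the 2 sets of cells is neither excluded nor singled out: 145 ribosomal protein and oxidative phosphorylation genes followed the median of their neighbours with a slope of 0.928 (95% interval 0.822 to 1.04; Pearson r 0.790, Spearman rho 0.781, permutation p = 0.0001, the smallest the permutations can give; across genes, which are not independent replicates), as they would under any cause that acts on whole regions. DNA was not analysed here, so copy number, other causes acting on regions, separate derivation of the cells and the knockdown itself remain open.

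Of the genes with a mean of at least 5 CPM, 72 differed at least 32-fold, 56 higher and 16 lower in shPRAME. Reads shared between near-identical copies are argued against, since 1 of 68 searched genes, or 1.47% (exact interval 0.0372% to 7.92%), had such a copy, namely U2AF1, and 2.0% of 500 other genes did. Less similar family members were not counted as copies, so reads shared with them stay open. Another cell population added to the shPRAME libraries would not remove transcripts, which argues against it for the 16 lower genes only. Of the 56 higher genes 2 are listed markers of another cell type (COL1A2, from 0 to 2157 counts, and LUM, from 1 to 992). The limits of 5 CPM and 32-fold leave out other markers. Of these, COL6A3 (971 to 15955 counts), COL3A1 (3 to 256), PDGFRA (362 to 1231) and TEK (3 to 281) also rose. So did PTPRC (0 to 92), LYZ (7 to 131) and CD68 (4275 to 7081). COL1A1 (11 to 49) and DCN (0 to 33) rose but stayed low. Fewer counts were found for PDGFRB (6262 to 1741), FAP (4488 to 2703), THY1 (6 to 2), CD14 (22 to 20) and CD79A (5 to 1). DCN, THY1, CD14 and CD79A are named after their values were seen. A mixed-in population stays open for the higher genes. A copy number difference of whole segments alone is argued against for these genes. Of 49 in a segment, 51.0% (exact interval 36.3% to 65.6%) moved the way of the segment, where that explanation needs them to do so. The difference from the 69.5% of other genes was -18.451 percentage points (Fisher's exact p = 0.00766). Segment medians come from those other genes too, which raises their share, so this p does not bear on the cause. The bound written beforehand was a difference within 15 points, and the value lay beyond it on the side opposite to the explanation. Segments held at least 20 genes, so losses or gains of fewer genes could not be seen and stay open. A difference in cell state between the 2 sets of cells, by loss of PRAME, by effects of the hairpin on other transcripts or by clonal origin, may remain, and was not tested.

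Some pairs of near-identical genes on chromosome 21 divided their counts differently in the 2 groups. Apart from U2AF1, the genes of these pairs are named after their values were seen. U2AF1 and its copy LOC102724594 had a log2 ratio of -0.36 as a sum, PWP2 and LOC102724159 -0.86, CBS and LOC102724560 -0.05, and SMIM11 and LOC102723553 -0.37, while single members ranged far wider, such as -2.95 for PWP2 and -2.54 for LOC102724560. ICOSLG and LOC102723996 were both lower, at 5.89 CPM together in shCtrl and 0.230 in shPRAME.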
